A study of Mus musculus with 3 samples.

How the data were processed

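The series maps where the transcription factor GATA4 sat on chromatin of the adult mouse stomach. The mice carried a GATA4 protein with a Flag and biotin tag together with the biotin ligase BirA, so that GATA4 and the DNA bound to it could be pulled down with streptavidin beads. Per the labels, stomach mucosa came from adults of 10 to 12 months, and there were 3 libraries: GATA4 pull-down replicates 1 and 2, and 1 input library of chromatin that was not pulled down. The labels name a different code for each pull-down, without saying whether these are separate animals, and the input shares its code with pull-down replicate 1.

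The submitters' processing notes name Bowtie2, MACS2 and HOMER and the mouse build mm9; a version was given only for MACS2, which was 2.1.0.20140616 per the file headers. Both pull-down libraries were pooled by the authors into 1 treatment set and called against the single input with a q-value limit of 0.05, per the file headers. The headers record 59610626 treatment tags and 28116789 input tags of 74 bases. The caller kept 1 tag per position, which left 38770530 and 23023152 tags. The share removed as redundant was 35.0% in the pooled pull-downs and 18.1% in the input. The larger set was scaled down to the smaller, per the file headers, so that 1 treatment tag counted as 0.594 in the deposited values, and tags were extended to 161 bp. The depth of each pull-down library by itself is not given in the sources used here.

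For each peak the deposited table gives the summit pileup, which is a coverage signal in scaled tags, the fold enrichment, which is a ratio of pull-down pileup to local input computed by the authors' peak caller, and the −log10 of the q-value. Peak length, summit position and distance to the nearest transcription start site (TSS) were used as deposited. All 50869 pileup values came to whole tags within 0.02 of a tag after division by the scaling factor. The deposited annotation table from HOMER adds an annotation class, the nearest TSS with its gene and a score; the score equalled 10 times the −log10 q-value cut to a whole number in all 50869 peaks. The names of 2 columns had been lost to spreadsheet errors, and one of them, the column of −log10 q-values, was identified by that match. Both tables gave the same coordinates for every peak. Coordinates are those of mm9, counted from 1. The input level behind a peak was recovered, with 1 added to it, as pileup plus 1, divided by fold, since the caller adds 1 to both sides of the ratio. The median of this sum of input level and 1 was 3.00.

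HOMER gives each peak to 1 gene, the owner of the nearest TSS, noncoding transcripts included. A gene described below as having no peak may therefore lie near a peak that is credited to another transcript. Gene names were taken by Entrez ID from a RefSeq gene table of assembly GRCm38.p6, which was used only for names, gene types and chromosomes. Of all peaks, 99.9% had an Entrez ID in that table. This also recovered 24 genes whose names the deposited table shows as dates, which covered 79 peaks. For 89 peaks of 28 genes, mm9 and the table placed the gene on different chromosomes; they were kept.

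The pooled call leaves no value per replicate, so no pull-down replicate could be compared with the other, no replicate could be left out, and no test between samples was possible. Tests below treat peaks or genes as units and describe this single list. Binomial intervals cover counting error only.

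The peak list was described by number, length, covered sequence and fold enrichment. Shares of annotation classes carry exact Clopper-Pearson 95% intervals. Fold enrichment was compared between peaks within 1 kb of a TSS and peaks over 10 kb away on the log2 scale with a two-sided permutation test of 100000 resamples. There were 19 gene lists, fixed from textbook knowledge before the data were examined: markers of pit mucous, neck and antral gland mucous, chief, parietal and gastric endocrine cells; intestinal and squamous forestomach genes; epithelial structure; foregut transcription factors; Wnt, Notch, hedgehog and BMP signalling; smooth muscle, fibroblast, endothelial, immune, enteric neural and glial, cardiac, hepatic and housekeeping genes; and, by symbol pattern, olfactory and vomeronasal receptors. Second symbols of a gene counted once, and all members were matched. The background was 21031 protein-coding genes with a curated RefSeq transcript. For each list, the share of members with a peak within 10 kb of the TSS was compared with all other background genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 19 lists. Among genes with such a peak, the median fold of the strongest peak per gene was ranked among 10000 random lists of the same size, which permutes list membership among those genes; 2 times the smaller tail share was taken as p and adjusted in the same way. Peaks less than a little over 12 kb apart, a gap fixed between the alternatives of 5 and 25 kb, were joined into groups and compared with 100 random placements of the peaks within the span of their chromosomes. On simulated lists of 20 genes over the 21031 genes, the list test called 74% of lists with a true share of 95% and 80% of lists with a true share of 25%, and 0.93% of lists drawn at the background share.

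Genes were named by a rule fixed before the data were examined: Gata4, Gata5 and Gata6; the genes nearest to the 10 strongest peaks by fold; the 5 genes with the most peaks; and, from each list, the 3 members with the strongest peak within 10 kb and the first 2 in alphabetical order without such a peak. Some genes that this rule takes are not reported here. Genes named outside the rule are marked as chosen after their values were seen. Peaks past other limits of strength, other distances, other backgrounds and other gaps were tried as alternatives. A background of only the genes named in the annotation is made of genes nearest to a peak, so it was left out of the ranges over alternatives. After the data were seen, alternatives with only distal peaks, without repeats and with a wider background were added. Among them are strong distal peaks, the 10% with the highest −log10 q-value among the 34727 peaks over 1 kb from a TSS, counted for a gene within 50 kb. Analyses of the GATA sequence motif were planned but not run, since no mm9 sequence was used here. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.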

Results

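GATA4 binding was mapped in the stomach mucosa of adult mice by chromatin immunoprecipitation and sequencing, with streptavidin pull-down of a biotin-tagged GATA4. The data comprised 2 GATA4 pull-down libraries and 1 input library, and the authors' caller pooled the 2 pull-downs into 1 peak list of 38770530 filtered tags against 23023152 input tags. The question was where GATA4 sits in the genome of this tissue and which genes lie near its sites. Fold enrichments are the authors' values for the pooled libraries over the input. They have no replicate error and serve here to describe and rank peaks within the list.

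GATA4 peaks lay mostly in introns and between genes, but most of the top 10% by −log10 q-value lay within 1 kb of a transcription start site (TSS). The list held 50869 peaks that covered 18.9 Mb, with a median length of 268 bp. Introns held 31.3% of the peaks (95% interval 30.9 to 31.7) and intergenic sequence 31.2% (30.8 to 31.6). Another 16.6% (16.3 to 16.9), or 8456 peaks, fell in the promoter class, 12.7% in exons and 3.70% in 5′ untranslated regions. Transcription end sites held 2.17%, 3′ untranslated regions 1.59% and noncoding transcripts 0.71%. These shares were not compared with the share of the genome in each class, so they show no preference for a class. By distance alone, 31.7% of the peaks were centred within 1 kb of a TSS, 22.9% at 1 to 10 kb and 45.3% farther away.

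Most peaks were modest in height. The median fold enrichment was 4.37 (quartiles 3.90 and 5.28), 30.3% of peaks reached 5-fold and 527 peaks, 1.04%, reached 10-fold. Median fold was 5.59 in 5′ untranslated regions and 5.28 in promoters, against 4.29 in intergenic sequence and 4.32 in introns. Peaks within 1 kb of a TSS averaged a log2 fold of 2.413 ± 0.441 (SD, n = 16142), and peaks over 10 kb away 2.095 ± 0.319 (SD, n = 23054). The difference of 0.32 (bootstrap 95% interval 0.31 to 0.33) is a ratio of 1.25, with a permutation p of 1e-05, the smallest that 100000 resamples can give. Of the top 10% of peaks by −log10 q-value, 5086 in number, 73.5% were centred within 1 kb of a TSS and 39.3% were in the promoter class. Genes were reached widely: 64.4% of 21031 protein-coding genes had a peak within 10 kb of the TSS, 57.4% had one within 1 kb and 18.0% had a top 10% peak within 10 kb.

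**Figure D1:**
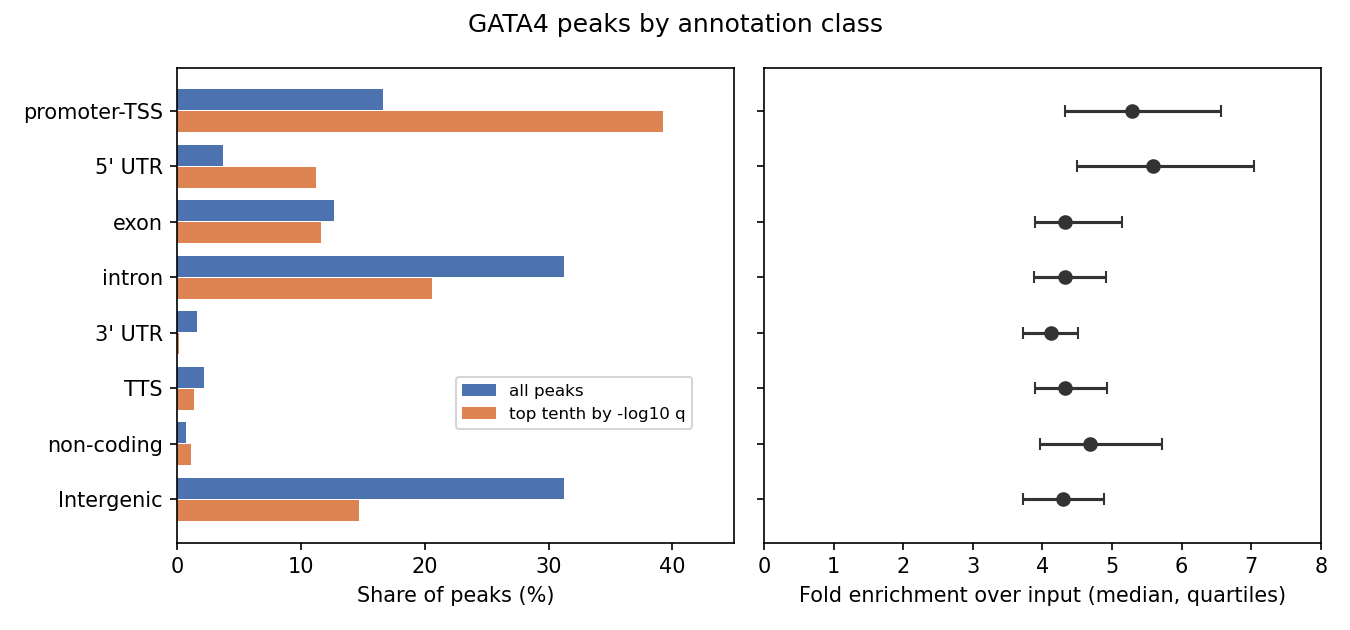
The left panel shows the share of peaks (%) in each annotation class for all 50869 peaks and for the top 10% by −log10 q-value; the right panel shows the median fold enrichment over input, with bars from the lower to the upper quartile. Promoters hold 16.6% of all peaks and 39.3% of the top 10%, and intergenic sequence 31.2% and 14.7%.

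GATA4 peaks lay around its own gene. Input was the only control library, so the peaks here and at the related genes are read as enrichment. Gata4 was the nearest gene of 16 peaks, 7 of them within 10 kb of its TSS on chromosome 14. The strongest, at 63874270 to 63875509, was intergenic, 10.8 kb upstream of the TSS, and reached 16.8-fold, which placed it 33rd in the whole list. A second upstream peak, 19.5 kb away, reached 9.04-fold. The peak over the Gata4 promoter (63863940 to 63864722) reached 8.70-fold, and a peak in exon 2 of 7 (63859310 to 63859972) reached 9.30-fold. The tagged protein is itself encoded there.

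The related factor genes Gata6 and Gata5 also had peaks. Gata6, on chromosome 18, had 9 peaks, 4 of them within 10 kb. An intergenic peak 131.7 kb upstream (10920551 to 10921000) reached 14.5-fold, and a peak 1.01 kb upstream (11051285 to 11051707), in intron 1 of the antisense transcript Gata6os, reached 9.45-fold. The peak over the Gata6 TSS itself (11052266 to 11053612) reached 16.3-fold, but the annotation credits it to the promoter of Gata6os, whose TSS lies beside that of Gata6. Gata5, on chromosome 2, had 10 peaks, 8 of them within 10 kb, and its promoter peak (180069204 to 180069826) was the strongest, at 7.06-fold. The other peaks of Gata5 reached 3.12-fold to 5.11-fold.

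**Figure D2:**
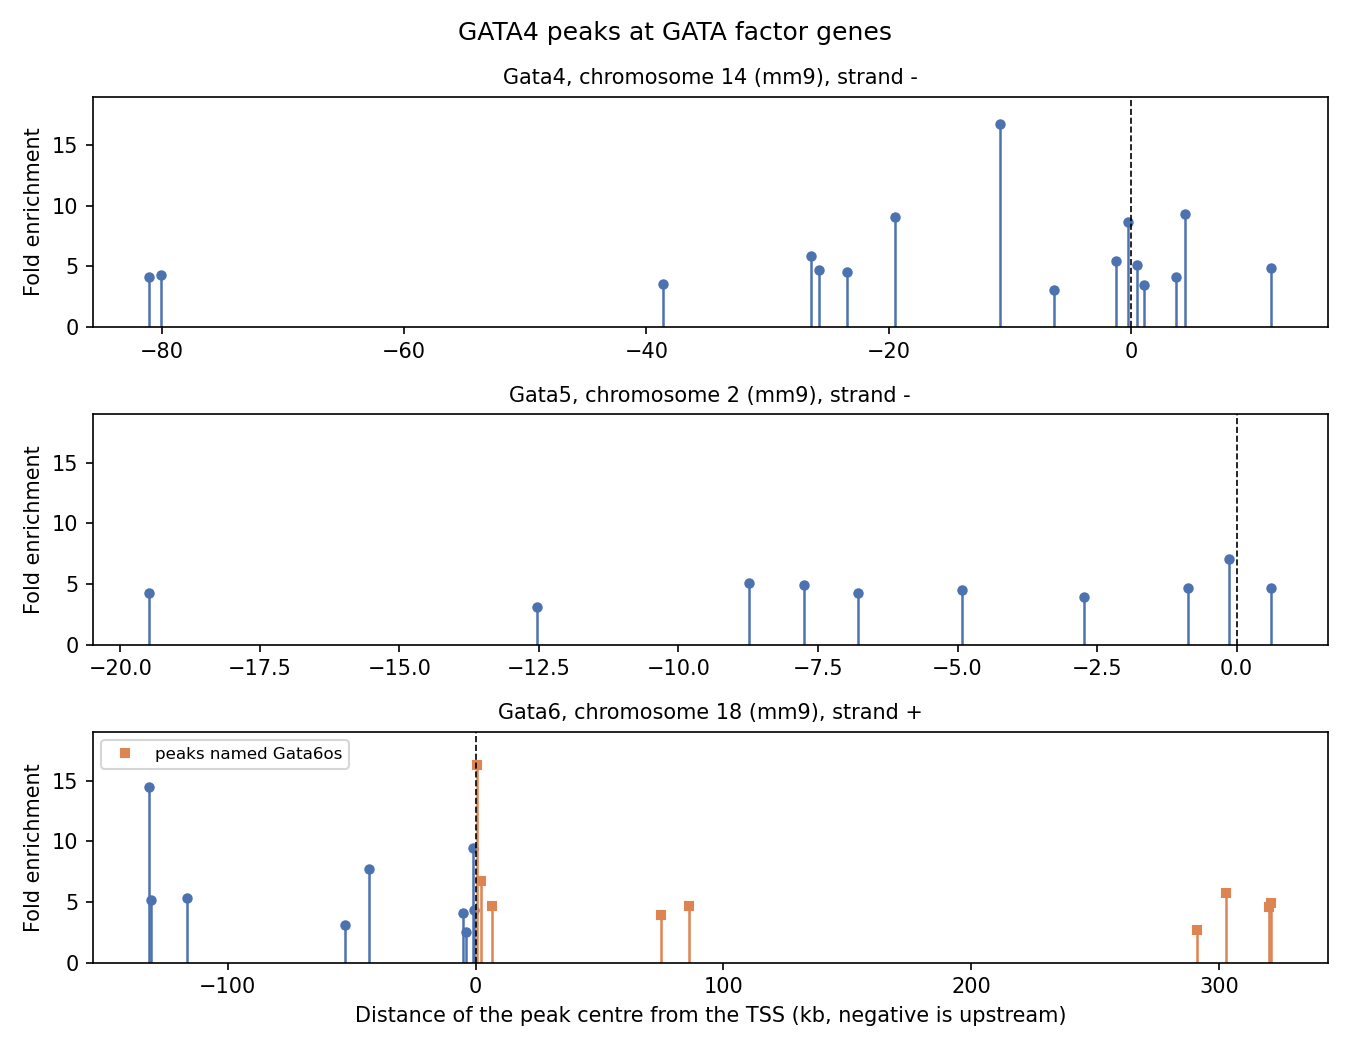
Each stem is a peak at Gata4, Gata5 or Gata6, placed by the distance of its centre from the TSS (kb, negative upstream) with its fold enrichment over input as height; squares are peaks that the annotation names for Gata6os. The tallest stems are the peak 10.8 kb upstream of Gata4 at 16.8-fold and the peak over the Gata6 TSS at 16.3-fold.

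Among the 10 strongest peaks was 1 at a gene for a direct GATA partner, Zfpm1, which encodes the cofactor FOG1. That peak lay in intron 2 of 9 (chromosome 8, 124830210 to 124831239), 24.7 kb from the TSS, at 21.7-fold. Soat1, which encodes a cholesterol-esterifying enzyme, had a 31.0-fold peak in intron 1 of 15 (chromosome 1, 158400647 to 158401120). A peak at the transcription end site of Lgals2, the gene of galectin-2 (chromosome 15, 78679966 to 78681774), reached 22.7-fold. Ypel2 had a 21.7-fold peak in intron 2. At promoters or first exons, Ints2, of the Integrator complex, reached 23.6-fold, and Cpox, of haem synthesis, 20.3-fold in exon 1 of 7 (chromosome 16, 58670066 to 58671072). Gm1968 was the nearest gene of an intergenic peak at 31.4-fold, 32.8 kb away on chromosome 16. The peak named for Golph3, at 21.1-fold, lay in exon 22 of 24 of Pdzd2, and the peak named for 9230112D13Rik, at 20.8-fold, in intron 8 of Ldb3. The strongest peak of all, at 32.6-fold near 4930517M08Rik (chromosome 17, 4626090 to 4626664), lay in a simple repeat.

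Genes of epithelial structure, foregut transcription factors and developmental signalling nearly all had GATA4 peaks. All 22 genes of epithelial structure had a peak within 10 kb (100%, exact 95% interval 84.6 to 100), against 64.3% of other genes (Fisher's exact test, adjusted p = 0.00028). The strongest were at Esrp2 (13.3-fold, 1.28 kb upstream) and Esrp1 (11.3-fold, 1.40 kb upstream), which encode epithelial splicing regulators, and at the promoter of Ezr, the gene of the microvillus protein ezrin (10.5-fold). Among the foregut transcription factors 32 of 33 had a peak (same exact test, adjusted p = 7.78e-05), led by the promoters of Runx1 (13.4-fold) and Ovol1 (10.1-fold) and the 5′ untranslated region of Klf5 (11.02-fold). The exception was Ehf, whose nearest credited peak was 17.4 kb away. Not counted here was the 16.3-fold peak over the Gata6 TSS, which the annotation credits to Gata6os. Of the genes of Wnt, Notch, hedgehog and BMP signalling, 33 of 34 had a peak (same exact test, adjusted p = 7.16e-05), with promoter peaks at Ctnnb1, which encodes β-catenin (15.7-fold), and at the BMP receptor gene Bmpr1a (14.2-fold), and an exon 1 peak at Ihh, which encodes Indian hedgehog (14.2-fold). Hhip, a hedgehog antagonist, was the nearest gene of no peak.

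Housekeeping genes also had peaks more often than other genes: 19 of 20 had one within 10 kb (Fisher's exact test, adjusted p = 0.0099), all but Pgk1, and their strongest were at the promoter of Polr2a (10.6-fold) and in the first intron of Ywhaz (10.5-fold). These 4 lists also had stronger peaks than random lists of their size. By permutation of list membership, the median strongest fold was 8.00 in housekeeping genes (adjusted p = 0.0019), 7.15 in foregut transcription factors (adjusted p = 0.0038), 6.89 in epithelial structure (adjusted p = 0.041) and 6.67 in signalling (adjusted p = 0.043), against 5.51 to 5.59 in random lists. Housekeeping genes no longer passed with peaks at any distance (exact test, adjusted p = 0.090) or, in a setting chosen after the data were seen, with only peaks 1 to 10 kb from the TSS (0.66). Over 6 alternatives fixed beforehand, the adjusted p of these exact tests ranged from 3.83e-05 to 0.0090 for epithelial structure, from 1.19e-05 to 0.00048 for foregut factors, from 9.35e-07 to 0.0031 for signalling and from 0.00017 to 0.090 for housekeeping genes.

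Markers of the gastric gland cells had GATA4 peaks near many genes, at shares within 10 kb that did not pass the test. A peak within 10 kb was present at 9 of 13 pit mucous genes, 8 of 12 neck and antral gland genes, 6 of 9 chief cell genes, 15 of 20 parietal cell genes and 12 of 18 endocrine genes. None of these 5 shares passed Fisher's exact test against other genes (adjusted p of 0.62 in parietal and 1 in the others). The simulated lists held 20 genes, and all of these lists but the parietal one were smaller. Their failure to pass is therefore no evidence against an excess. With peaks at any distance, all 20 parietal genes had one (same exact test, adjusted p = 0.012, range over its alternatives fixed beforehand 0.012 to 1). The nearest credited peak lay 26.6 kb from Aqp4 and 74.2 kb from Kcne2. The count at any distance depends on the space around a gene, which was not measured. With only peaks 1 to 10 kb from the TSS, a setting chosen after the data were seen, 8 pit (adjusted p = 0.028), 7 neck (0.044) and 10 parietal genes (0.044) had one, more than other genes in the same exact test. This was not particular to gastric markers, since squamous forestomach and cardiac genes passed there too, as given below. In the pit list the surface mucin gene Muc1 had an 18.5-fold peak at its transcription end site, 4.74 kb from the TSS (chromosome 3, 89037345 to 89038085). Foxq1, a regulator of surface mucin, had an 11.5-fold peak in its exon, and Gkn2, which encodes a gastrokine, an intergenic 8.25-fold peak 7.40 kb away. In the neck list the mucous cell factor Spdef had a 12.4-fold peak 5.67 kb upstream, the gland mucin gene Muc6 a 6.91-fold peak 6.38 kb upstream, and the water channel gene Aqp5 a promoter peak of 6.51-fold. The chief cell genes were led by Xbp1 (8.27-fold, exon 1), the pepsinogen C gene Pgc (7.50-fold, exon 4 of 9) and the promoter of Bhlha15 (5.31-fold). The parietal list was led by the carbonic anhydrase gene Car2 (7.62-fold), the potassium channel gene Kcnq1 (7.52-fold at the promoter) and Atp4a, which encodes the catalytic subunit of the proton pump (7.38-fold, 5.55 kb upstream). The endocrine list was led by Isl1 (10.9-fold, promoter), Insm1 (6.91-fold) and Pax6 (6.67-fold). No peak within 10 kb was credited to Anxa10, Ctse, Agr2, Aqp4 or Kcne2, whose nearest credited peaks lay farther away. A4gnt, Cblif, Chia1, Ghrl and Hdc were the nearest gene of no peak at any distance.

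With the setting chosen after the data were seen, strong distal peaks within 50 kb, the pit mucous list was the only gland cell list that passed. Such a peak was near 8 of 13 pit genes, or 61.5%, against 8.15% of other genes (Fisher's exact test, adjusted p = 8.36e-06). The pit list was not tested against any other list. Besides the Muc1 and Gkn2 peaks given above and a Foxq1 peak 10.4 kb upstream (6.31-fold), it was found at Muc5ac, the main surface mucin gene, at 12.6-fold and 17.8 kb upstream (chromosome 7, 148956801 to 148957364). It was also found at Ctse (6.51-fold, 23.7 kb away), Psca (5.71-fold), Gkn1 (5.19-fold) and Tff1, genes named because they make up the count. The annotation places Tff1 at 2 sites, and such a peak lay about 4.9 kb upstream of both, at 5.71-fold on chromosome 17 and 6.51-fold on chromosome 5. The gene table used for names places Tff1 on chromosome 17 only. The site on chromosome 5 may be a second copy in the mm9 build, so the 2 peaks may not be independent. With the same setting and exact test, 16 of 33 foregut factors (adjusted p = 1.1e-08), 11 of 22 genes of epithelial structure (adjusted p = 2.05e-06) and 9 of 34 signalling genes (adjusted p = 0.0049) had such a peak more often than other genes. The shares of 5 of 20 parietal (adjusted p = 0.063), 3 of 12 neck (0.16), 4 of 18 endocrine (0.15), 2 of 9 chief (exact, adjusted p = 0.28) and 4 of 20 housekeeping genes (adjusted p = 0.16) did not pass. Among these were Atp4a, Hrh2, Kcnq1, Ppargc1a and Slc26a9 in the parietal list, Agr2, Muc6 and Spdef in the neck list, Insm1, Isl1, Nkx6-3 and Pax6 in the endocrine list, Pgc and Xbp1 in the chief list, and Actb, Rplp0 and Ywhaz in the housekeeping list. Among members chosen after their values were seen, Ezr had an 18.5-fold peak in intron 1, 15.8 kb from the TSS, and Cldn3 a 10.4-fold peak 11.8 kb upstream. Other strong distal peaks lay little over 1 kb from a TSS, as at Gata6 (1.01 kb) and Cldn7 (1.04 kb), so the setting does not exclude promoter signal.

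Immune, hepatic and olfactory or vomeronasal receptor genes had GATA4 peaks less often than other genes. Immune genes had a peak within 10 kb at 4 of 21 (Fisher's exact test, adjusted p = 0.00013), namely Gata2 (11.7-fold, 8.99 kb upstream), Kit (5.48-fold), Spi1 (5.11-fold) and, named to complete the count, Gata3 (4.12-fold). Adgre1 had none. Hepatic genes had one at 5 of 20 (same exact test, adjusted p = 0.0017), led by Cyp3a11 (4.92-fold, in an L1 repeat), Apoa2 (4.69-fold) and Pck1 (4.52-fold); Ttr (4.41-fold) and G6pc (2.93-fold) complete the count. Afp and Ahsg were the nearest gene of no peak at any distance. Within 1 kb both lists lay below other genes (exact test, adjusted p = 0.0012 and 0.00052), but with only peaks 1 to 10 kb from the TSS neither passed (0.66 and 0.40), nor did either with strong distal peaks (1 and 1), settings chosen after the data were seen. Among the settings fixed beforehand, the immune list no longer passed with top 10% peaks (exact test, adjusted p = 0.23; range over its alternatives 2.43e-05 to 0.23), and the hepatic list with top 10% peaks (0.087; range 0.00044 to 0.087), within 50 kb (0.062) or at any distance (0.060). Of 1463 olfactory and vomeronasal receptor genes, which belong to multigene families, 93 or 6.36% (5.16 to 7.73) had a peak within 10 kb, against 68.7% of other genes, an odds ratio of 0.031 by Fisher's exact test. Their median strongest fold was 4.32, and 2 of their 3 strongest peaks, at Vmn2r72 and Olfr854, lay in repeats. The third was at Olfr750, at 7.90-fold, and Olfr1 and Olfr10 had none.

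The other lists did not pass the test within 10 kb. Intestinal genes had a peak at 14 of 30 (Fisher's exact test, adjusted p = 0.13), led by the promoter of the guanylin gene Guca2a (9.30-fold), Apoa4 (6.47-fold) and Anpep (6.07-fold), while Apob and Cdh17 had none that near. Within 1 kb of the TSS, this list lay below other genes (exact test, adjusted p = 0.019; range over its alternatives 0.019 to 1), and so it did within 10 kb without olfactory and vomeronasal receptors in the background (0.041). Squamous forestomach genes had one at 13 of 24 (exact test, adjusted p = 0.56), led by Pitx1 (7.90-fold), Lypd3 (5.91-fold) and Lor (5.51-fold); Col17a1 and Dsc3 had none. Their direction depended on distance: this list lay below other genes within 1 kb (5 of 24, exact test, adjusted p = 0.00098; range over its alternatives fixed beforehand 0.00098 to 1) and above them at 1 to 10 kb (12 of 24, exact test, adjusted p = 0.044). The latter setting was chosen after the data were seen, and with strong distal peaks the list did not pass above other genes. Smooth muscle genes had one at 8 of 15, with Tpm1 (6.87-fold), Smtn (5.70-fold) and Myl9 (4.92-fold) ahead and none at Acta2 or Actg2. Fibroblast genes had one at 9 of 15, led by the promoter of Fbln1 (7.90-fold), Twist1 (5.88-fold) and Vim (4.92-fold), with none at Col1a2 or Col3a1. Endothelial genes had one at 7 of 15, led by Esam (5.71-fold), Sox17 (5.12-fold) and Cldn5 (4.92-fold), with none at Cdh5 or Emcn. Enteric neural and glial genes had one at 10 of 15, led by Ret (6.47-fold), Tubb3 (6.27-fold) and Elavl3 (6.11-fold), with none at Chat or Nos1. Cardiac genes, a class that GATA4 regulates in the heart, had one at 12 of 20, among them Nkx2-5 (6.47-fold) and Tbx20 (5.31-fold), with none at Actc1 or Actn2. This list too lay below other genes within 1 kb (6 of 20, exact test, adjusted p = 0.040; range 0.040 to 1) and above them at 1 to 10 kb, the setting chosen after the data were seen (10 of 20, exact test, adjusted p = 0.044), but did not pass above them with strong distal peaks. The adjusted p of these 5 lists were 0.67, 1, 0.38, 1 and 0.95 in Fisher's exact test.

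**Figure D3:**
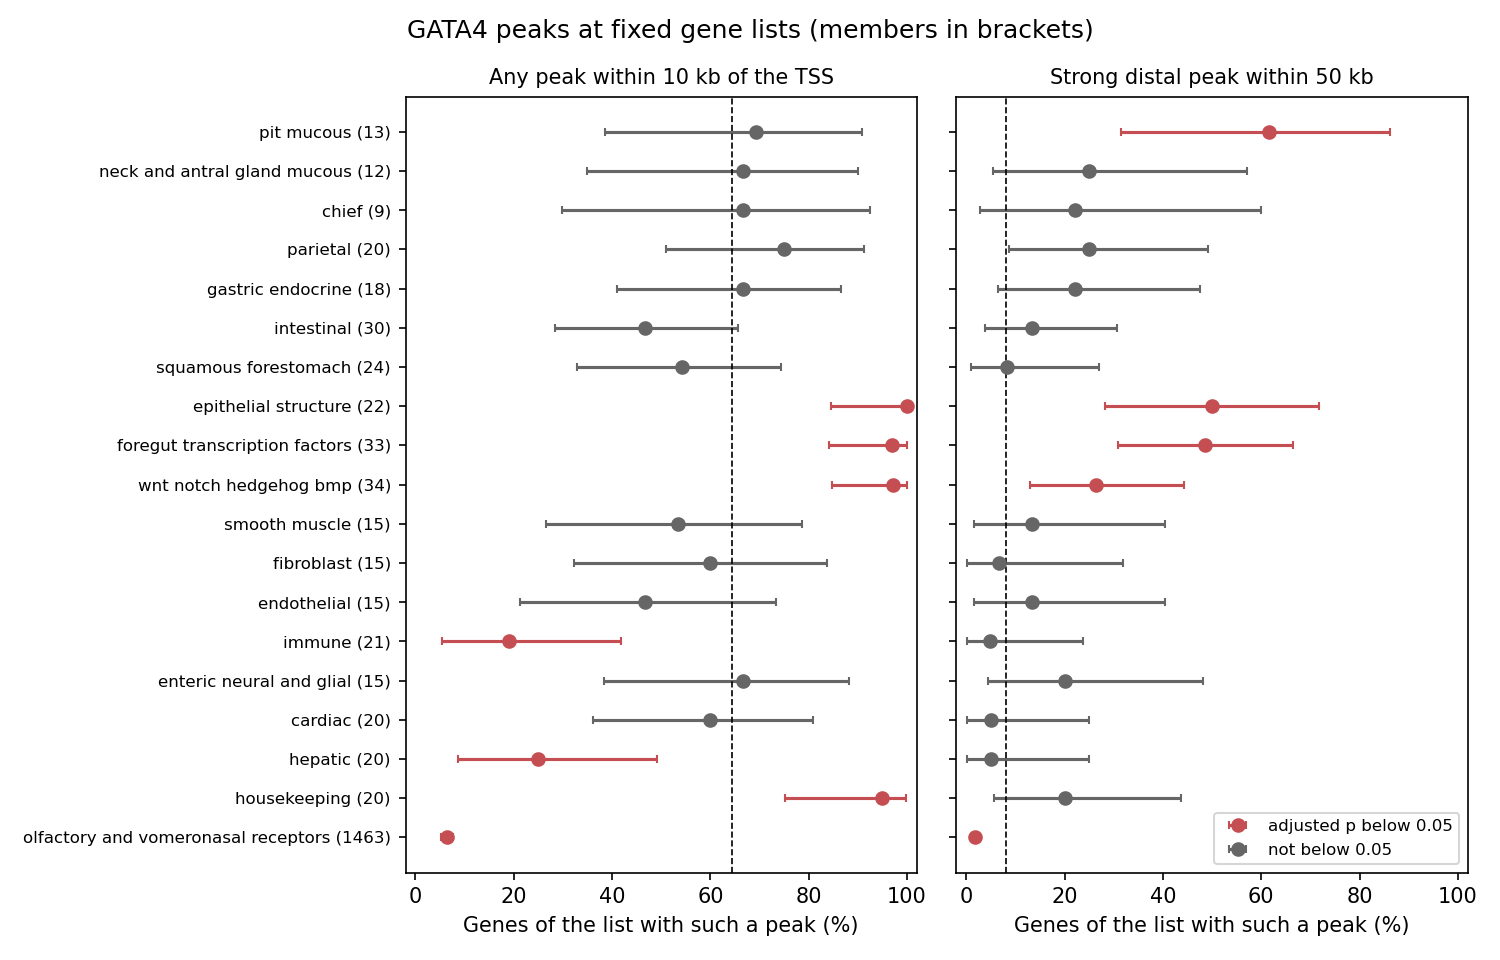
Points show the percentage of genes of each list with any GATA4 peak within 10 kb of the TSS (left) or a strong distal peak within 50 kb (right), with exact 95% intervals; the dashed lines mark the share among all background genes (left, 64.4%) and the median share of the genes outside a list (right). The lists that passed the test above other genes are epithelial structure, foregut factors, signalling and housekeeping genes on the left, and epithelial structure, foregut factors, signalling and pit mucous genes, at 61.5%, on the right; further lists lie above a line without passing.

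GATA4 peaks were crowded into groups. With neighbours up to a little over 12 kb apart joined, 8878 groups of 2 or more peaks held 69.3% of all peaks, where random placements gave a mean of 9087 groups with 41.9%. Groups of 10 or more peaks numbered 580, with 19.1% of the peaks, against a mean of 0.47 and at most 3 such groups in 100 random placements. The placements were even along each chromosome and ignored where genes lie. The excess therefore cannot be credited to GATA4 in particular. The largest, with 100 peaks, spanned 20 genes on chromosome 10 (80679684 to 80898405). Zfpm1 lay in a group of 58 peaks on chromosome 8 (124778141 to 124880470), and 9 of its own peaks were strong distal ones. Gse1 lay in a group of 62 peaks. The genes with the most peaks were Hrh1 with 126, the repeated small RNA gene Rn4.5s with 73, the zinc finger gene Casz1 with 59, Gse1 with 57 and Atg7 with 52. Casz1 had its strongest peak, at 14.5-fold, in intron 4 of 20, and Gse1 its strongest, at 13.9-fold, 71.9 kb upstream. Of the Hrh1 peaks, 81 lay on unplaced sequence, where a single offset placed 46 of the 84 summits of a dense group within 100 bp of summits on chromosome 6. With a gap of 5 kb, groups of 10 or more numbered 184.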

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

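The tests of input level at LINE copies, of peak strength against housekeeping genes, of other tissues' markers, of the parts of the epithelial lists and of both explanations for the Hrh1 groups were chosen only after the result was seen, and so was the setting of strong distal peaks. No outlier among samples was sought, since the list pools the libraries.

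The main comparisons of the report did not separate peaks by the repeat annotation, which placed 6077 peaks, 11.9% of the list, in LINE repeats. Their median fold was 4.24, and 1.23% of them were in the top 10% by −log10 q-value, against 4.65% of peaks outside repeats and over 1 kb from a TSS. Of the LINE peaks 92.1% fell in the young L1Md subfamilies, led by L1Md_T with 2849 peaks and L1Md_A with 1599. Reads spread over near-identical copies would give this, which makes such spreading a candidate explanation. Binding in these subfamilies would give it too, and the share of L1Md in LINE sequence was not compared, so the value cannot decide. Low input at these copies predicted a lower share of LINE peaks with an input level above the genome-wide floor. The share was higher, at 33.4% against 23.7% of peaks outside repeats and over 1 kb from a TSS (Fisher's exact test, p = 3.38e-52). Levels below that floor cannot be recovered from the peak values, so the test cannot decide about low input at the remaining LINE peaks. Whether GATA4 binds L1 sequence was not tested, because neither the sequence nor the reads were used here.

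Another 286 peaks lay on unplaced or randomly placed sequences, and 84 of these formed a dense group whose nearest genes were Hrh1 and Mucl2, while a group of 92 on chromosome 6 (114442974 to 114593303) had Atg7 and Hrh1 as nearest genes. A single offset placed 46 of the 84 summits, 54.8%, within 100 bp of a summit of the chromosome 6 group, where 100 random redraws of the summits reached at most 26. The shared pattern may come from reads divided between 2 assembled copies of a sequence. More copies of this stretch in a pull-down sample than in the input would make the enrichment even along it; the labels do not say whether the samples come from separate animals. The highest fold over the median fold was 1.49 in the unplaced group, below the 1.67 to 5.03 of 8 other large groups, and 1.85 on chromosome 6, within that range, so that explanation cannot be told apart from local enrichment with pooled values.

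The strongest peak of the list, at 32.6-fold, lay in a simple repeat on chromosome 17, and the main comparisons did not separate peaks by repeats. Simple repeats held 178 peaks, of which 16.3% were in the top 10% by −log10 q-value.

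Together, the 5 gastric cell-type lists, epithelial structure and foregut factors had a peak within 10 kb at 104 of 127, or 81.9%, against 64.3% of other genes (Fisher's exact test, p = 2.3e-05), carried by epithelial structure and foregut factors with 54 of 55 (exact p = 1.72e-09), since the cell-type markers had one at 50 of 72 (exact p = 0.39). A pull-down of any active promoter predicted no excess over housekeeping genes in peaks 1 to 10 kb from the TSS. Such peaks were near 58.3% of all these genes and 36 of the 55, against 6 of the 20 housekeeping genes (Fisher's exact test, p = 0.028 and 0.0086). The cell-type markers taken alone, with 38 of 72, did not pass (exact p = 0.082). These peaks were not particular to the lists, since 12 of 24 squamous forestomach and 10 of 20 cardiac genes had one too. Some lay little over 1 kb from a TSS, as at Esrp2 (1.28 kb) and Esrp1 (1.40 kb), so the comparison cannot exclude promoter pull-down. Promoter pull-down also stays open within 10 kb. There the 54 of 55 did not pass against the 95% of housekeeping genes (exact p = 0.46), and the 50 of 72 markers lay below it (exact p = 0.020). The difference in mean log2 strongest fold, epithelial minus housekeeping, was −0.25 (permutation p = 0.0328). Strong distal peaks were near 38.6% of the 127 genes, against 8.00% of other genes (Fisher's exact test, p = 2.26e-21) and 4 of the 20 housekeeping genes (exact p = 0.14; 0.033 for the 27 of 55 genes of epithelial structure and foregut factors, 0.41 for the 22 of 72 markers), so that GATA4 sites of the gastric epithelium remain a hypothesis, found and tested on the same list. Strong distal peaks were near 9.09% of 121 markers of other tissues against 30.6% of the 72 gastric cell-type markers (Fisher's exact test, p = 0.00026). The other tissues were smooth muscle, fibroblast, endothelial, immune, enteric neural and glial, cardiac and hepatic, without the intestinal and squamous forestomach lists. Wide space around tissue-specific genes of any kind predicted no such difference. The space around genes was not measured, so the comparison cannot exclude it. Some strong distal peaks, too, lay little over 1 kb from a TSS, as at Esrp2 and Esrp1, so they cannot exclude promoter pull-down.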

How the results depend on the processing

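Alternatives limited to distal peaks, without repeats or unplaced sequences, with all protein-coding genes as background, and without genes placed on another chromosome in the reference table were chosen after the data were seen. No paired analysis was possible because the authors pooled both pull-downs and the groups share only replicate number 1. For the same reason no replicate was left out; the motif alternatives were not run, since no mm9 sequence was used here. The promoter peaks stayed stronger than distal ones in all 5 other settings. The peak count fell to 25434 above the median fold and 5086 in the top 10%, by construction. The promoter share was 31.7% by distance to the TSS, 24.0% above the median fold, 39.3% in the top 10% and 20.7% without repeats and unplaced sequences. The number of lists past the threshold, 7, was 3 when only genes named in the annotation formed the background, by construction: this background holds only genes nearest to a peak, 87.3% of which outside the epithelial structure list had one within 10 kb, so it says nothing about how stable the lists are. Groups of 10 or more peaks numbered 184 with a gap of 5 kb. With peaks 1 to 10 kb from the TSS, 2 lists turned direction and passed the threshold: squamous forestomach genes lay 24.0 points above other genes (Fisher's exact test, adjusted p = 0.044) and cardiac genes 24.0 points (adjusted p = 0.044). Intestinal (10.7 points), smooth muscle (20.7), endothelial (7.34) and fibroblast genes (0.67) also lay above other genes there, after lying below them within 10 kb, but passed in neither setting; other sign changes of lists that passed in neither setting are not listed. The cause was not tested. Of the other list results, 103 kept their side of the threshold under the other settings fixed beforehand, 5 gained a call and 5 lost it; under the later settings 93 kept theirs, 7 gained a call and 12 lost it. The single input and pooled calls limit every value, since the spread between samples is unknown.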

Other observations

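The tests by gene family below were chosen after the data were seen. Gene symbols that share a root were taken as a family, and the 163 families of at least 15 background genes were tested by Fisher's exact test with Benjamini-Hochberg adjustment. A peak within 10 kb was present more often than at other genes in 39 families and less often in 41, the latter with the olfactory receptors and the unnamed Gm genes. Of 42 β-defensin genes (Defb) 1 had a peak, of 34 secretoglobin genes (Scgb) 2, of 26 prolactin-family genes (Prl) 1 and of 22 major urinary protein genes (Mup) 1, with adjusted p of 4.33e-16, 2.42e-11, 1.68e-09 and 7.46e-08. These were Defb7, Scgb1b30, Scgb1c1, Prl3d3 and Mup8, and all of them belong to multigene families. Peaks of the top 10% by −log10 q-value were more frequent than at other genes in 15 families and less frequent in 19. They lay within 10 kb of 20 of 42 Ube genes, which encode ubiquitin-conjugating enzymes and relatives (47.6%, exact test, adjusted p = 0.00035), 30 of 77 Ppp genes of protein phosphatases (39.0%, adjusted p = 0.00045) and 13 of 24 Zdhhc palmitoyltransferase genes (54.2%, adjusted p = 0.0013). Collagen genes (Col) had such a peak at 0 of 44 (exact test, adjusted p = 0.0037). With any peak within 10 kb they did not pass (25 of 44, 56.8% against 64.4%, exact test, adjusted p = 0.43).

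Strong distal peaks within 50 kb gave another picture, though some lay little over 1 kb from a TSS, as at Nr2f2 (1.08 kb) and Cldn7 (1.04 kb). Apart from the olfactory receptors and Gm genes, which had fewer, 2 of the 163 families passed, both above other genes. Of 26 Nr nuclear receptor genes 9 had such a peak (34.6% against 8.16%, exact test, adjusted p = 0.0076), led by Nr4a3 at 11.9-fold and 2.11 kb upstream and by the glucocorticoid receptor gene Nr3c1 at 10.0-fold and 2.51 kb upstream. Of 34 claudin genes (Cldn), which encode tight junction proteins, 10 had one (29.4%, exact test, adjusted p = 0.011). Among these 10 were Cldn15 at 8.90-fold, Cldn18, the gastric claudin, at 7.30-fold in an intron, and Cldn3, Cldn4 and Cldn7. Cldn18, Cldn3, Cldn4 and Cldn7 are also in the list of epithelial structure. With any peak within 10 kb the claudin family lay below other genes without passing (16 of 34, 47.1% against 64.4%, exact test, adjusted p = 0.081). So it did with top 10% peaks (3 of 34, 8.82% against 18.0%, exact test, adjusted p = 0.38).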
